A study of Solanum lycopersicum with 8 samples.

How the data were processed

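Total RNA of young leaves and anthers of 8-week-old tomato plants was sequenced by massive analysis of cDNA ends, in which poly(A) RNA is bound and the last 500 bp at the 3′ end are sequenced, per the labels' protocols. Plants grew under 16 h of day at 24 °C and 8 h of night at 20 °C, and stressed plants were moved to a growth chamber at 120 μmol m−2 s−1 of light. Anthers of several developmental stages were collected, per the labels. Each library was deposited by the authors as a table of CPM values (tags scaled to a total of 1000000, called TPM in the tables) with no gene length term. FastQC is the tool named in the submitters' processing notes, and the aligner, counting method, genome build and annotation are not given in the sources used here.

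The values show how they were scaled. In each library most values above 0 are multiples of 1 step, and 1000000 divided by that step, rounded, was taken as the number of reads in the library. It ranged from 6243965 (A2AS heated leaf) to 14764187 (A2AS control anther). The 29345 listed genes held 69.2% to 73.4% of each library. Between 77.6% and 83.9% of the values above 0 were whole reads within 0.001 of a read, below the 95% set for recovering counts, so no count model was run. Why the other values are not whole reads was not tested. How reads matching several genes were counted is not given in the sources used here, so single values of near-identical family members are less certain than those of the group. Whether the counting used strand is not stated, so reads of a gene and an antisense transcript cannot be told apart. A change in total, or in a few abundant genes, moves every other value: the 100 most abundant genes held 20.8% to 39.1% of the listed reads.

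Groups were taken from the labels by tissue, genotype and treatment, with 1 library in each of 8 groups. No 2 libraries held an identical value above 0 in the 9441 genes compared. Ratios were computed as log2 of (value + 1) over (value + 1), which understates the change of low genes, and folds in the text are ratios of the values themselves. Genes with a pair mean of at least 10 CPM were counted as different at 2-fold or more. Counts and medians of gene lists use all measured members, without this minimum, and the text gives the values with it where a printed 2-fold count changes. Exact (Clopper-Pearson) 95% intervals were computed from values turned into reads and rounded to whole reads. They cover counting error only, since reads without molecular identifiers are not independent molecules.

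The tests used limma on log2(value + 1) over all 8 libraries, for genes with a mean of at least 2 CPM, with empirical Bayes variances that follow the mean and Benjamini-Hochberg adjustment at 0.05. Heat was tested with the tissue and genotype pair as a block, A2AS with the tissue and treatment pair as a block, and the difference of the heat ratio between tissues with the genotypes as the only repeats. The residual of the main effects is thus how a response varies over tissues and genotypes or treatments, not a spread between replicate plants. The corresponding differences of A2AS between tissues and of heat between genotypes were added after the data were seen.

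Gene names were the main limit on description. None of the 41476 rows of the reference gene table held an ID of the form used in the files, and the files do not pair IDs with names. The 69 IDs in 12 of the 24 gene lists were written down from published tomato nomenclature before the data were examined, and all 69 were found. Their names and list membership rest on that nomenclature and not on the deposited tables. The other 12 lists depended on descriptions and could not be used. For each list the median log2 ratio was placed among 10000 random lists matched in 20 bins of mean expression, where at least 3 members were measured. DREB2A, the only listed gene of the AP2/ERF group, stayed at or below 0.892 CPM in all libraries.

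Genes named were chosen by a rule fixed before the data were examined. It takes HsfA2 first, then other Hsf genes reaching 10 CPM. For heat in each WT tissue it takes the 10 largest rises and 5 largest falls of at least 2-fold that go the same way in the A2AS pair. For A2AS it takes, per tissue, the 10 heat-raised genes with the most reduced and the 5 with the most increased rise, and the 5 highest and 5 lowest by the mean of the control and heat log2 ratios. It also takes the 10 highest in anther and 5 highest in leaf, 2 to 4 members of each list with the widest ratios, and the 5 smallest adjusted p values per direction and test. As no table gives names, at most 2 unlisted IDs were printed in each direction per comparison. Listed genes followed through comparisons in which they were not among the widest ratios of their list, and Solyc08g082820, were chosen after their values were seen.

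The pair step was tested on simulated libraries with counting noise, and the limma step on simulated data with 200 changed genes and a coefficient of variation of 14.1%. A changed gene had the same fold in every pair in which it was changed. The shares recovered thus do not cover responses that vary between those pairs. For heat, limma recovered 46.0% of genes changed 1.5-fold and 100% of those changed 2-fold, with 5 unchanged genes called among 15181. For heat by tissue it recovered 36.0% at 2-fold, 100% at 4-fold and 96.0% at 8-fold, with 7 unchanged genes called among 15192.

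Alternatives were pseudocounts of 0.5 and 5, no minimum, a minimum of 50 (10 for limma), median-ratio scaling, totals without the 100 most abundant genes, a 4-fold threshold, additive terms in place of the pair, and each pair left out in turn. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.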

Results

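Expression was measured by massive analysis of cDNA ends (MACE), which sequences the 3′ end of polyadenylated RNA. The 8 libraries came from young leaves and anthers of tomato cv Moneymaker, from wild type (WT) plants and from plants labelled A2AS, known from the study as transgenic plants with suppressed HsfA2. Heat-stressed plants spent 1 h at 39 °C and recovered for 1.5 h at 24 °C, and the handling of the control plants is not described in the labels. Each of the 8 combinations of tissue, genotype and treatment had 1 library, so no pair of libraries has a replicate check. Library size was 6243965 reads in heated A2AS leaf and 11534512 to 14764187 in the other libraries. Levels are given in CPM (tags scaled to 1000000 per library), and 3 reads corresponded to 0.203 to 0.480 CPM. Intervals in brackets are 95% exact counting intervals and cover counting error only.

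HsfA2, the heat stress transcription factor targeted in the A2AS plants, was reduced in A2AS leaf but not in the heated anther library labelled A2AS. In leaf it stood at 10.3 CPM in WT control and 21.7 in WT heat, against 2.25 and 2.72 in the libraries labelled A2AS. WT was thus 4.59-fold (3.07 to 7.06) higher in control leaf and 7.98-fold (4.90 to 13.9) higher in heated leaf. In anthers HsfA2 was at 1.93 CPM in WT control and 1.08 in A2AS control, a ratio whose interval includes 1 (1.78-fold, 0.909 to 3.59). After heat it reached 22.3 in WT anthers and 39.3 in the anther library labelled A2AS, which was 1.76-fold (1.53 to 2.03) higher. The heated anther level therefore goes against the label, and directions drawn below from the heated anther library labelled A2AS carry that limit. HsfA3 was at 38.8 and 51.8 CPM in WT control and heated leaf, and at 10.2 and 22.7 in WT control and heated anthers. HsfA7 went from 1.21 to 9.62 in WT anthers and from 1.69 to 12.0 in anthers labelled A2AS, while in leaf it stayed between 1.56 and 3.84. HsfA1a lay between 17.1 and 27.2 CPM in all 8 libraries.

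**Figure D1:**
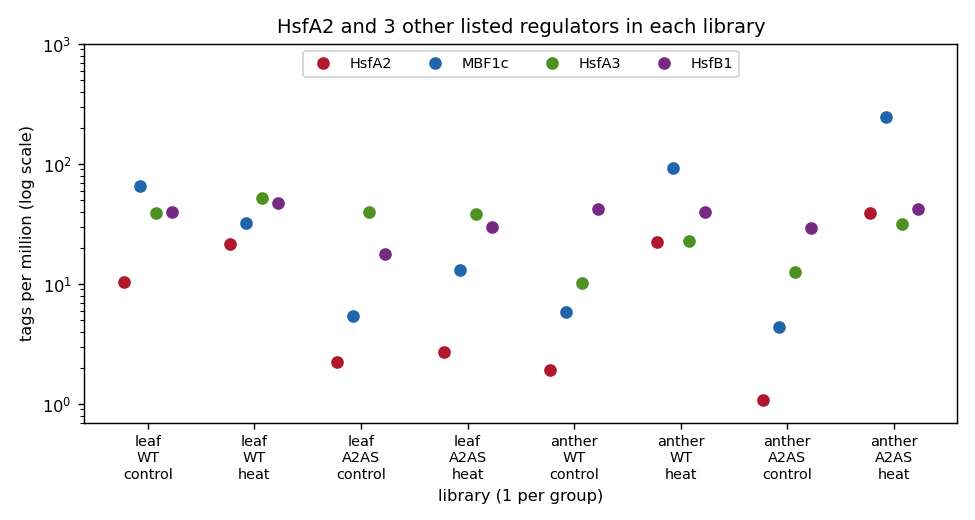
CPM (log axis) of HsfA2, the coactivator MBF1c, HsfA3 and HsfB1 in each of the 8 libraries, with 1 point per gene and library. HsfA2 lies at 2.25 and 2.72 in the A2AS leaf libraries and at 39.3 in the heated anther library labelled A2AS.

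Among the listed groups, the small heat shock proteins, chaperones that bind unfolding proteins, had the largest median rise after heat in leaf. All 12 listed members were at least 2-fold higher after heat in WT leaf, with a median log2 ratio of 3.39, and all 12 were so in A2AS leaf, with a median of 4.70 (11 of 11 at a pair mean of at least 10 CPM). Solyc03g082420 went from 242 to 4221 CPM in WT leaf, a 17.4-fold (16.8 to 18.1) difference, and from 25.8 to 741 in A2AS leaf, a 28.7-fold (25.8 to 32.1) difference. Of the 9 listed HSP70 and BiP genes, 4 were at least 2-fold higher in WT leaf, but 1 of them, Solyc01g099660, only reached 2.24 CPM. The count was 3 of 8 at a pair mean of at least 10 CPM, 3 of 9 under median-ratio scaling and 2 of 9 with a pseudocount of 5. Solyc11g066060 was 4.05-fold (3.88 to 4.24) lower. The HSP90 gene Solyc06g036290 was 5.40-fold (5.05 to 5.78) higher in WT leaf and 19.4-fold (16.3 to 23.2) higher in A2AS leaf. HSP101 (Solyc03g115230), a disaggregase, was 3.60-fold (3.27 to 3.98) and 6.68-fold (5.46 to 8.22) higher. The larger ratios in A2AS leaf start from lower control levels: 10.4 CPM against 87.2 in WT for Solyc06g036290, and 9.35 against 43.4 for HSP101. After heat both were also lower in A2AS, at 201 CPM against 471 and 62.5 against 156. MBF1c differed in direction: it was 2.04-fold (1.81 to 2.30) lower after heat in WT leaf and 2.39-fold (1.72 to 3.31) higher in A2AS leaf. Here too the control level was lower in A2AS leaf, at 5.44 CPM against 65.5 in WT. After heat MBF1c was still lower in A2AS leaf, at 13.0 CPM against 32.0. Over both tissues its heat ratio did not pass the limma test of a difference between genotypes (adjusted p = 0.370 by limma over its list, of which it is the only member). Among genes for which the files do not pair IDs with names, Solyc01g103920 was 56.6-fold (43.5 to 75.1) and Solyc04g014480 31.2-fold (28.8 to 33.8) higher in WT leaf. Solyc12g040790 was 6.81-fold (6.14 to 7.58) and Solyc03g097580 6.28-fold (4.76 to 8.40) lower.

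By the fixed 2-fold rule, 501 of 8833 genes differed between heated and control WT leaf (354 higher, 147 lower) and 304 of 8153 in A2AS leaf (215 higher, 89 lower). Under median-ratio scaling the WT leaf split was 269 higher and 229 lower, and the median of all genes moved from 0.10 to −0.02 log2. Between WT and A2AS leaf, 139 genes were higher after heat in both pairs, where 6.71 would be shared by independent lists. The medians of the small heat shock proteins lay at percentile 100 of 10000 matched random lists in both pairs.

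In anthers the small heat shock proteins were again the listed group with the largest median rise. All 12 members were at least 2-fold higher after heat in WT anthers (median log2 ratio 6.57) and in anthers labelled A2AS (median 6.13). Solyc08g062340 went from 13.1 to 2133 CPM in WT anthers, a 163-fold (139 to 191) difference, and from 17.2 to 1818 in the libraries labelled A2AS, a 106-fold (93.7 to 121) difference. HSP101 was 18.3-fold (16.5 to 20.4) higher in WT and 21.5-fold (19.6 to 23.7) higher in A2AS anthers. The HSP70 gene Solyc03g117630 was 68.8-fold (59.6 to 79.7) and 64.8-fold (57.7 to 73.1) higher. MBF1c was 15.8-fold (12.4 to 20.2) and 55.9-fold (43.8 to 72.6) higher. Markers of the anther itself moved less: MS10 and MS32, regulators of tapetum development, were 1.66-fold (1.40 to 1.99) and 1.34-fold (1.14 to 1.59) higher after heat in WT anthers. LAT52, a pollen-expressed gene, was 2.77-fold (2.61 to 2.95) lower after heat in WT anthers and 1.20-fold (1.13 to 1.27) higher in those labelled A2AS. Solyc03g113930 and Solyc01g102960, which the files do not name, were 183-fold (139 to 245) and 153-fold (136 to 172) higher in WT anthers. Solyc02g078250 was 18.4-fold (16.6 to 20.5) lower in WT and 20.3-fold (17.9 to 23.2) lower in A2AS anthers. Solyc01g068120 was 20.2-fold (15.8 to 26.2) lower in WT, against 1.04-fold (0.930 to 1.17) in A2AS.

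In total 485 of 9288 genes differed at least 2-fold after heat in WT anthers (237 higher, 248 lower) and 448 of 9485 in anthers labelled A2AS (211 higher, 237 lower). At 4-fold the split was 78 higher and 99 lower in WT, and it turned to 83 higher and 34 lower in A2AS. The 2 anther pairs shared 140 higher genes, where 4.88 would be shared by independent lists, and 96 lower genes against 5.41. A further 32 genes were at least 2-fold higher after heat in WT and at least 2-fold lower in A2AS.

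**Figure D2:**
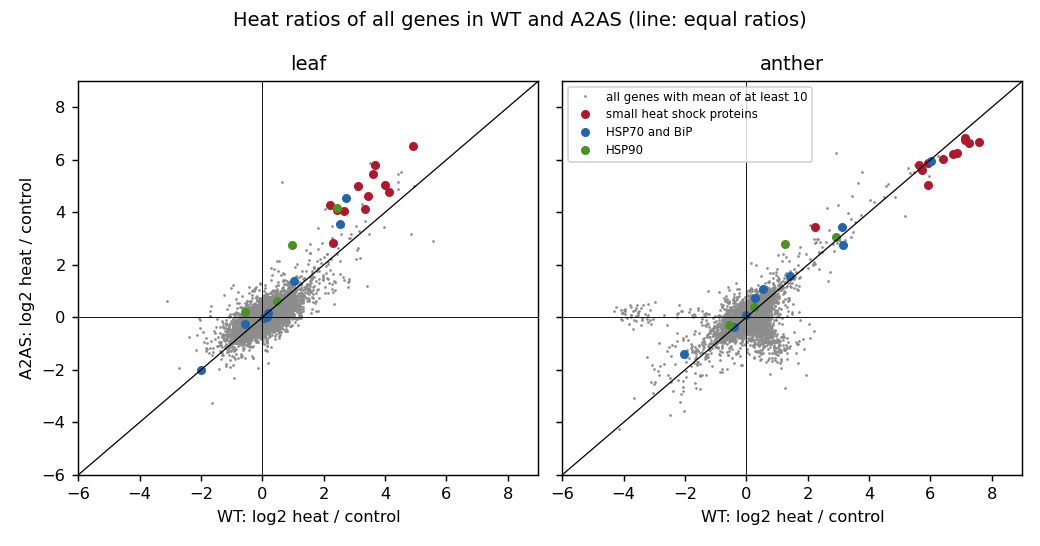
Log2 ratio of heat to control in WT (x axis) against A2AS (y axis) for genes with a mean of at least 10 CPM over the 4 libraries of leaf (left) or anther (right). The line marks equal ratios, and colours mark the listed chaperones. The small heat shock proteins sit near medians of 3.39 (WT) and 4.70 (A2AS) in leaf and of 6.57 and 6.13 in anther.

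Over the 4 heat-control pairs, all 12 small heat shock proteins rose by limma, among all genes tested and adjusted over the list alone. Solyc03g082420 rose by 5.08 ± 0.27 log2 (SE; limma adjusted p = 0.000775) and was higher in 4 of 4 pairs. Of 9 HSP70 and BiP genes 4 were called (5 adjusted over the list alone). Solyc04g011440 rose by 3.16 ± 0.17 (adjusted p = 0.000775), while Solyc11g066060 fell by 1.85 ± 0.13 (limma adjusted p = 0.00244) and was lower in 4 of 4 pairs. Both listed HSP100 genes rose, and 2 of 4 HSP90 genes did (3 adjusted over the list alone). None of the 12 Hsf genes above the expression minimum was called by limma, with 0 adjusted over the list alone and 8 at an unadjusted p under 0.05. HsfA2 differed by 2.12 ± 0.63 log2 (adjusted p = 0.119). Of 8 reference genes TIP41 fell, by 0.69 ± 0.10 (adjusted p = 0.0261; 2 genes adjusted over the list alone). By limma no call was made among all genes for MBF1c or the 2 ascorbate peroxidases (1 each at an unadjusted p under 0.05 and 1 each adjusted over the list alone). None was made for the 3 small subunit genes of Rubisco (1 at an unadjusted p under 0.05) or for LAT52, MS10 and MS32 (0), with 0 adjusted over the list alone.

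The limma test of heat called 399 of 15220 genes (284 higher, 115 lower). Under median-ratio scaling it called 206 higher and 262 lower, and leaving out any 1 pair left 56 to 131 calls. With no expression minimum it called 51. By the size rule, 61 of 6814 genes were higher in all 4 pairs, against 0.00139 under independence, and 4 were lower.

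The heat response differed between the tissues for some chaperones. The heat ratio of Solyc06g076540 was larger in anther than in leaf by 4.56 ± 0.35 log2 (SE; limma adjusted p = 0.0187), that of Solyc08g062340 by 3.58 ± 0.45 (adjusted p = 0.0379) and that of HSP101 by 2.05 ± 0.27 (adjusted p = 0.0397). In all, 4 of 12 small heat shock proteins were called among all genes, each with the larger ratio in anther, and 12 adjusted over the list alone. Of those 12, Solyc05g014280 had the larger ratio in leaf (−2.87 ± 0.60 log2, anther minus leaf; limma adjusted p = 0.0930 among all genes). A larger ratio is not a higher level after heat, since all 12 started at least 2-fold lower in WT control anther than in WT control leaf. In heated WT plants some were higher in leaf, such as Solyc03g082420 (4221 CPM against 1327 in anthers). Others were higher in anthers, such as Solyc08g062340 (2133 CPM against 539 in leaf). For HSP70 and BiP the counts were 0 and 5 of 9, with Solyc08g082820 going the other way from the rest. For Hsf genes they were 0 and 3 of 12, namely HsfA2, HsfA3 and HsfA7, and for MBF1c 0 and 1 of 1. Among all genes 145 were called (55 with the larger ratio in anther, 90 in leaf). This count rests on single pairs: it was 0 without WT leaf, 3 without A2AS leaf, 608 without WT anther and 668 without A2AS anther. It was also 2 with additive terms and 0 with no expression minimum.

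In leaf, the chaperone groups had negative medians in A2AS against WT, in unheated and heated plants, where the median of all genes was also below 0. Against matched random lists, the small heat shock proteins lay at percentile 0 in control and heated leaf, HSP70 and BiP at 0 and 0.03, and HSP90 at 0 and 5.02. The last lies within the range of 95% of random lists (−0.81 to 0.48), so the HSP90 median in heated leaf (−0.71) is not particular to the group. All 12 small heat shock proteins were at least 2-fold lower in A2AS control leaf (median log2 ratio −2.45; 11 of 11 at a pair mean of at least 10 CPM, and 11 of 12 with a pseudocount of 5), and 4 of 12 were in heated leaf (median −0.95; 2 under median-ratio scaling). Solyc03g082420 was 9.39-fold (8.41 to 10.5) lower in control and 5.70-fold (5.53 to 5.87) lower in heated A2AS leaf. The WT control leaf level of this group was itself above that of anthers: all 12 were at least 2-fold lower in WT control anther than in WT control leaf (median −2.67; 11 of 11 at that minimum, and 11 of 12 with the pseudocount of 5). HSP100 had medians of −1.43 (1 of 2 at least 2-fold lower) and −1.71 (2 of 2). HSP70 and BiP had medians of −0.93 and −0.98, and 4 of 9 were at least 2-fold lower in each comparison, among them Solyc06g076020 (5.48-fold, 4.37 to 6.95, in control leaf). Of 4 HSP90 genes 3 were at least 2-fold lower in control leaf and 2 in heated leaf (2 and 0 under median-ratio scaling). MBF1c was 12.0-fold (9.49 to 15.5) lower in control and 2.47-fold (1.95 to 3.17) lower in heated leaf. The Rubisco small subunit genes, which encode part of the carbon-fixing enzyme, went the other way: RBCS1 was 2.76-fold (2.71 to 2.80) higher in A2AS control leaf and 3.72-fold (3.65 to 3.79) higher in heated leaf. Among genes the files do not name, Solyc01g081250 was 59.6-fold (48.1 to 74.7) and Solyc06g069730 13.3-fold (12.4 to 14.2) higher in heated A2AS leaf. Solyc02g081550 was 12.6-fold (9.80 to 16.5) and Solyc01g105350 12.5-fold (8.52 to 19.1) lower.

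**Figure D3:**
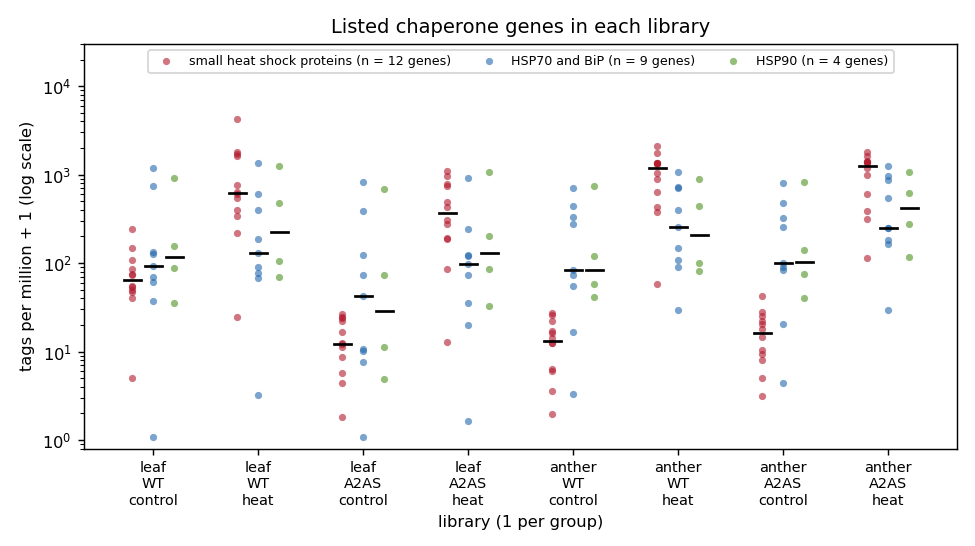
CPM plus 1 (log axis) of the listed small heat shock proteins, HSP70 and BiP, and HSP90 genes in each of the 8 libraries, with 1 point per gene and a black bar at the median of the group. All 12 small heat shock proteins are at least 2-fold lower in A2AS than in WT control leaf, and all 12 are at least 2-fold higher after heat in each of the 4 pairs.

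In control leaf 391 of 8331 genes differed at least 2-fold between A2AS and WT (161 higher, 230 lower), and in heated leaf 868 of 8727 (300 higher, 568 lower). The scaling sets the direction of these splits. The median of all genes was −0.21 log2 in control and −0.32 in heated leaf, and −0.01 and −0.05 under median-ratio scaling, where the splits became 283 higher and 132 lower, and 519 higher and 232 lower. Without the 100 most abundant genes in the total they were 245 and 152, and 462 and 282. At 4-fold the control split was 10 higher and 42 lower, and the heated split 52 higher and 38 lower. Across genes the 2 leaf comparisons, which share no library, correlated at Pearson's r = 0.772, with genes not being independent replicates.

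In anthers the chaperone medians of A2AS against WT were at or above 0, except where scaling is named. The median log2 ratio of A2AS to WT was 0.40 in control anthers (0.22 over the 8 members with a pair mean of at least 10 CPM) and 0.03 in heated anthers for the small heat shock proteins (−0.04 under median-ratio scaling in the heated pair), with 0 of 12 members at least 2-fold different in either. HSP70 and BiP had medians of 0.18 and 0.40, HSP90 of 0.20 and 0.52, and HSP100 of 0.00 (−0.07 under median-ratio scaling) and 0.72. Against matched random lists, the small heat shock proteins lay at percentile 99.99 in control and 12.1 in heated anthers, HSP70 and BiP at 95.1 and 99.99, and HSP90 at 91.8 and 99.91. In heated anthers 1 of 4 HSP90 and 1 of 2 HSP100 genes were at least 2-fold higher. In the heated anther library labelled A2AS, MBF1c was 2.66-fold (2.49 to 2.83) and the HSP90 gene Solyc03g007890 2.83-fold (2.66 to 3.01) higher than in WT. LAT52 was 2.17-fold (2.05 to 2.29) lower in A2AS control anthers and 1.53-fold (1.43 to 1.63) higher in heated ones. MS10 was 1.59-fold (1.28 to 1.98) and 1.55-fold (1.32 to 1.83) lower in control and heated anthers. Solyc01g081250 was 28.1-fold (26 to 30.4) higher in heated anthers and 3.0-fold (2.29 to 4.05) higher in control anthers, and Solyc05g045670 was 7.77-fold (6.71 to 9.04) and 6.92-fold (6.02 to 8.03) higher. Solyc10g054900 was 6.58-fold (5.17 to 8.47) lower in control and 5.29-fold (4.0 to 7.11) lower in heated anthers.

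At least 2-fold differences between A2AS and WT were found for 186 of 9213 genes in control anthers (64 higher, 122 lower) and 217 of 9476 in heated anthers (87 higher, 130 lower). The heated split turned to 31 higher and 6 lower at 4-fold, and to 273 higher and 236 lower with no minimum. Only 4 higher and 16 lower genes were shared between the 2 comparisons (0.519 and 1.26 under independence), while 38 were higher in control and lower in heated anthers and 29 the reverse. Across genes the 2 comparisons correlated at Pearson's r = −0.147.

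No gene was called for A2AS over the 4 genotype pairs by limma, among 15220 tested, with 1313 at an unadjusted p under 0.05. HsfA2 differed by −1.03 ± 0.48 log2 (SE; limma adjusted p = 0.597). Solyc05g045670 and Solyc12g006530 shared the smallest limma adjusted p, at 0.216. Solyc05g045670 had a difference of 2.20 ± 0.26 and higher values in A2AS in 4 of 4 pairs. Solyc12g006530 went the other way, with lower values in A2AS in 4 of 4 pairs. Adjusted over the list alone, 2 of 3 Rubisco small subunit genes were called and no member of the other lists tested. On simulated data, with the same fold in all 4 pairs, this limma test recovered 94.0% of genes changed 2-fold and 54.0% of those changed 1.5-fold. The real A2AS ratios hardly correlated between leaf and anther (Pearson's r = −0.024 in control and 0.003 in heated plants). Those shares therefore do not say how many A2AS effects confined to 1 tissue would be found.

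The rise of heat-raised genes was compared between the genotypes by size only. In leaf, 45 of 327 genes raised in WT had a ratio at least 2-fold smaller in A2AS, and in the mirrored comparison 46 of 237 genes raised in A2AS had one at least 2-fold smaller in WT. These were 29 and 51 under median-ratio scaling and 154 and 83 with no minimum, so the larger side in leaf depends on the settings. In anthers the counts were 72 of 242 and 20 of 208. Among the 72 are the 32 genes that were at least 2-fold higher after heat in WT and at least 2-fold lower in A2AS. The anther counts carry the limit of the heated anther label. An exchange of labels or a different mix of anther stages cannot be told apart from a weaker rise in A2AS. None of the listed chaperones was among the 10 with the most reduced rise in A2AS in either tissue. Outside those 10, the HSP100 gene Solyc02g088610 rose less in A2AS leaf, by 1.47 log2 against 2.83 in WT leaf. In anthers it went the other way, with 2.41 in the libraries labelled A2AS against 1.21 in WT. Among the 5 with the most increased rise were the small heat shock proteins Solyc06g076560 and Solyc09g015020 in leaf (by 2.14 and 2.09 log2), and MBF1c and the HSP90 gene Solyc03g007890 in anthers (by 1.75 and 1.54). These leaf ratios start from lower control levels in A2AS (7.67 CPM against 48.9 in WT, and 3.41 against 46.5). After heat both leaf genes were still lower in A2AS (489 CPM against 639, and 84.7 against 216). In anthers the most reduced rise was that of Solyc07g056300, which went from 35.5 to 141 CPM in WT and from 126 to 26.5 in the libraries labelled A2AS. The heat ratio differed by genotype for 0 of 15220 genes by limma (228 at an unadjusted p under 0.05), a test added after the data were seen. Adjusted over the list alone, 1 of 4 HSP90 genes was called, Solyc03g007890, with a ratio larger in A2AS by 1.65 ± 0.20 log2 (limma adjusted p = 0.00117), and no member of the other lists. In leaf Solyc03g007890 stood at 3.84 and 31.6 CPM in A2AS control and heat, against 34.6 and 69.3 in WT. In anthers it stood at 38.9 and 277 in the libraries labelled A2AS, against 40.4 and 97.9 in WT.

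Anther and leaf differed widely in unheated WT plants. LAT52 was 200-fold (125 to 344) higher in anther, and MS10 and MS32 stood at 16.0 and 19.2 CPM there against 0.0867 and 0.260 in leaf. RBCS3 was 76.6-fold (73.7 to 79.7) and RBCS2 3.55-fold (3.50 to 3.61) higher in leaf. HsfA2 was 5.34-fold (3.42 to 8.65) and MBF1c 11.1-fold (8.74 to 14.4) higher in leaf, and HsfB1 stood at 41.9 and 40.1 CPM in anther and leaf. Among genes without names, Solyc06g069220 was 335-fold (232 to 504) and Solyc02g078050 827-fold (323 to 3036) higher in anther. Solyc08g082120 was 117-fold (92.2 to 150) and Solyc04g007790 103-fold (93.2 to 113) higher in leaf. In all 3581 of 9289 genes differed at least 2-fold (1782 higher and 1799 lower in anther), and the median of all genes moved from 0.11 to −0.04 log2 under median-ratio scaling.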

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

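Of the tests in this part, those of the difference of A2AS between tissues, of heat by tissue with pairs left out, and of scaling, HsfA2 level, exchanged labels, transgene reads, anther stage mix and sample splits were chosen after the results were seen. No group had enough libraries to look for a library far from the others.

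Leaf and anther differed in their heat ratio for 145 genes by limma, including HSP101 (2.05 log2 larger in anther), Solyc06g076540 (4.56), Solyc06g076570 (1.93), Solyc08g062340 (3.58) and Solyc11g020330 (2.95). The count was 0 without WT leaf, 3 without A2AS leaf, 608 without WT anther and 668 without A2AS anther, and 2 with additive terms in place of the pair and 0 with no minimum. The A2AS effect differed between tissues for 464 genes. The log2 ratio of A2AS to WT was higher in anther than in leaf for 306 of them and lower for 158. Median-ratio scaling gave 112 higher and 462 lower. The 464 calls became 0 without either leaf pair, 1138 without control anthers and 889 without heated anthers, and 0 with additive terms or with no minimum, which ends every call named here. Among them were Solyc03g082420 (2.83 log2), Solyc06g076520 (1.93), Solyc06g076020 (2.80), Solyc04g011440 (2.47), Solyc10g086410 (2.16), Solyc11g066060 (1.35), HSP101 (1.90) and RBCS1 (−1.54).

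Of the lists with at least 3 measured members, 5 had a negative median in both leaf genotype comparisons and a positive one in both anther comparisons, and of the smaller lists the 2 HSP100 genes and the 2 antioxidant genes did too. The difference, anther minus leaf, was 1.91 log2 for small heat shock proteins, 1.25 for HSP70 and BiP, 1.70 for HSP90, 0.37 for Hsf genes and 0.29 for reference genes, and it was not tested on the medians. The reference genes show how far scaling alone reaches: their leaf medians of −0.12 and −0.23 became 0.08 and 0.05 under median-ratio scaling. The small heat shock proteins in heated anthers then went to −0.04.

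Other splits of the 8 libraries into 4 and 4 were fitted like the heat test, and 3 of 35 could not be. Of the 32 fitted, the real one included, 1 gave as many calls as the real 399, and the highest other, 81, follows heat within anthers only. Splits that keep a pair together rest on fewer pairs, and the 8 that part every pair, where the highest other gave 0, are too few for a share under 0.05. For A2AS the real count was 0, which all 32 splits reach by construction, so the splits say nothing about chance there. The highest other, 3966, parts only the leaf pairs and follows A2AS against WT within leaf, a structure of the samples.

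The small heat shock proteins were lower in A2AS than in WT control leaf (median −2.45 log2). Scaling of the libraries is argued against, since the median was −2.25 under median-ratio scaling. A partial heat response in the WT control plants may contribute. Of the unlisted genes at least 4-fold higher after heat in both anther pairs, 23 had a pair mean of at least 10 CPM in control leaf. All 23 were lower in A2AS control leaf (100%, against 72.2% of all genes at that minimum). After median-ratio scaling 95.7% were, with a median of −0.82 log2 against −0.01 for all genes. A high WT control level helps a gene to pass that minimum. Below it, Solyc01g081250 went the other way, at 3.64 CPM in WT and 9.60 in A2AS control leaf. Lower HsfA2 in A2AS leaf would lower the same genes and stays open. The list was at 0.40 in control anthers, but HsfA2 was too low there (1.93 CPM in WT) to decide, and with 1 library per group the explanations cannot be told apart.

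HsfA2 was 39.3 CPM in the heated anther library labelled A2AS and 22.3 in WT, and transgene reads at an equal level in all A2AS libraries are argued against, since the other A2AS libraries held at most 2.72 CPM and the excess was 17.0. An exchange of the labels of the 2 heated anther libraries cannot be told apart from true labels: of 22 genes at least 1.5-fold different in the same direction in the other 3 genotype pairs, after centring on the median ratio, 14 kept it (63.6%, exact binomial interval 40.7% to 82.8%). At 0.8 log2 all 5 genes kept it and at 1 log2 both of 2, Solyc01g081250 (28.1-fold higher in the library labelled A2AS) and Solyc05g045670 (7.77-fold), which go with the label but are too few to decide. Against the label, 38 and 29 genes differed in opposite directions in control and heated anthers and 4 and 16 in the same (Pearson's r = −0.147, against 0.772 in leaf), which an exchange would give, as would the explanations of these genes below. Transgene reads that differ by tissue, and weak suppression in heated anthers, were not tested.

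In anthers 67 genes differed between the genotypes in opposite directions in control and heated plants. The counting intervals of 100% of them excluded 1 in both pairs, but the choice of genes at 2-fold and 10 CPM fixes that outcome, so it decides nothing. A different mix of anther stages or cell types between libraries is a candidate explanation: 95.5% were at least 4-fold higher in anther than in leaf libraries, against 11.5% of all genes compared, and the labels say that several stages were collected. The share was not set against other genes that differ between anther libraries. It therefore does not favour this explanation over the others given here. For the 29 that were lower in A2AS control the median CPM was 70.7 in WT control, 4.59 in WT heat, 28.6 in A2AS control and 32.2 in A2AS heat, and for the other 38 it went the opposite way (13.2, 31.4, 32.9 and 11.2), while LAT52, the pollen marker (295, 106, 136 and 163), went the way of the 29 and MS10, the tapetum marker (16.0, 26.7, 10.1 and 17.2), that of neither. A heat response that depends on genotype stays open, since only 2 of the 67 had a leaf mean of at least 10 CPM and 1 of them (50%) had the same sign there, and so does the exchange of labels above, under which heat would take the 38 from 13.2 to 11.2 in WT and from 32.9 to 31.4 in A2AS, and the 29 from 70.7 to 32.2 and from 28.6 to 4.59, though choosing genes by opposite directions fixes that the genotypes then go the same way.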

How the results depend on the processing

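Leaving out pairs in the heat by tissue test, and everything on the A2AS by tissue and heat by A2AS tests, was chosen after the data were seen. No list median of at least 1 log2 in size reversed its direction, but the larger side of some counts turned. The direction of single genes was not compared between the alternatives. Median-ratio scaling turned both leaf A2AS counts, the limma heat calls and the A2AS by tissue calls, and totals without the 100 most abundant genes turned both leaf A2AS counts. The 4-fold threshold turned heat in A2AS anther (83 higher, 34 lower), A2AS in heated leaf (52 and 38) and A2AS in heated anther (31 and 6). A minimum of 50 turned heat in WT anther (93 and 89) and A2AS anther (91 and 63), and a pseudocount of 5 the latter (167 and 165). No minimum turned A2AS in heated anther (273 and 236) and anther against leaf (3996 and 3133), and made the leaf genes raised less in A2AS more than those raised less in WT (154 and 83), a pseudocount of 0.5 turned anther against leaf (1832 and 1821), and leaving out A2AS leaf turned heat by tissue (2 and 1). Among the counts and tests that answer a comparison, 68 alternative values stayed within 1.5 times the reported one and 59 moved, and of the other values 251 stayed and 64 moved. Counts of genes at least 2-fold different are given in the order heat in WT leaf, A2AS leaf, WT anther and A2AS anther, A2AS in control leaf, heated leaf, control anther and heated anther, and anther against leaf. With no minimum they were 871, 638, 1056, 875, 759, 1568, 364, 509 and 7129, where more genes were counted, and at a minimum of 50 they were 207, 105, 182, 154, 139, 345, 60 and 61, and 1269, where fewer were. At 4-fold they were 88, 63, 177, 117, 52, 90, 12, 37 and 1723. With a pseudocount of 5, A2AS gave 575 in heated leaf and 116 in control anther. Genes raised less in A2AS numbered 26 in leaf and 37 in anther with a pseudocount of 5, 154 and 119 with no minimum, 14 and 17 at a minimum of 50, and 2 and 3 at 4-fold, and 29 in leaf under median-ratio scaling. Those raised less in WT numbered 28 and 14 with a pseudocount of 5, 83 and 62 with no minimum, 25 and 8 at a minimum of 50, 5 and 1 at 4-fold, and 51 and 22 under median-ratio scaling. The limma heat test called 255 genes with a pseudocount of 5, 51 with no minimum, 198 with additive terms, and 56 to 131 with a pair left out. Heat by tissue called 0 with no minimum, 2 with additive terms, and 0 to 668 with a pair left out, where the lone pair of a tissue is assumed to vary like the other tissue. A2AS by tissue called 168 with a pseudocount of 5, 0 with no minimum, 853 at a minimum of 10, 0 with additive terms, and 0 to 1138 with a pair left out. The A2AS and heat by A2AS tests called 0 under every alternative run. Apart from the number of genes counted, the cause was not tested. The edgeR quasi-likelihood and DESeq2 alternatives were not run, since only 77.6% to 83.9% of values above 0 were whole reads. At 3 reads, or 0.203 to 0.480 CPM, genes near the floor such as DREB2A give no usable ratio.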

Other observations

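The ID neighbour test in this part was set out before its result was seen, and its repeat without listed genes and the choice of genes to describe came afterwards. The ascorbate peroxidase gene APX2, which removes hydrogen peroxide, was at 251 CPM in WT control leaf and 155 in A2AS control leaf, a 1.62-fold (1.53 to 1.71) difference, and at 336 and 191 after heat. In anthers it stood at 254 and 318 in control and at 430 and 412 in heated libraries of WT and A2AS. HsfB1 was 2.26-fold (1.94 to 2.66) lower in A2AS than in WT control leaf and 1.44-fold (1.26 to 1.64) lower in A2AS control anthers. After heat it was 1.59-fold (1.35 to 1.88) lower in A2AS leaf, and 1.07-fold (0.953 to 1.20) higher in the anther library labelled A2AS. Solyc02g088610, the other listed HSP100 gene, was 4.36-fold (3.96 to 4.81) lower in heated A2AS leaf than in WT. It was 2.20-fold (2.03 to 2.39) higher in the heated anther library labelled A2AS. The small heat shock protein Solyc05g014280 went with leaf: it reached 1608 CPM in heated WT leaf and 57.4 in heated WT anthers.

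Of the 61 genes at least 2-fold higher after heat in all 4 pairs, 17 were on the lists. The hypothesis set out was that heat-raised genes lie at neighbouring IDs. Of the 61, 7 had another of the set within 5 listed IDs, against a median of 2 in 1000 random sets of equal size, which reached at most 8. Of the 7, 5 were listed small heat shock proteins, Solyc06g076520, Solyc06g076560 and Solyc06g076570, and Solyc09g015000 and Solyc09g015020. These IDs were already neighbours on the list written down beforehand, so for them the excess over random sets largely restates the list. Without the listed genes 2 of 44 remained, Solyc01g095320 and Solyc01g095340, and 318 of 1000 random sets had as many, so nothing is shown for heat-raised genes in general. How reads matching several copies were counted is not given, so this does not separate shared regulation from shared reads.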
